A study of Danio rerio and Aquarana catesbeiana with 12 samples.

How the data were processed

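Zebrafish RPE was dissected after 3 weeks of thyroid hormone or vehicle, and dorsal and ventral RPE was dissected from bullfrogs, per the labels' protocols. RNA was taken with a column kit for zebrafish and by phenol/chloroform for bullfrog, with DNase treatment in both. Zebrafish libraries were made with an amplification kit from total RNA, and bullfrog RNA was depleted of ribosomal RNA, so the species were analysed apart. Per the labels, the 6 samples of each species shared a sequencing lane. Per the submitters' processing notes, the tools included Bowtie 0.12.7 and edgeR. The genome build or transcript set is not given in the sources used here.

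Each species had 1 table of the whole series, and columns were matched to samples by title. The authors deposited raw counts per feature and library, which were whole numbers and summed to the totals in the report. In the bullfrog table the authors' deposited counts have commas within the digits, which were removed. The authors also deposited an RPKM value per feature as a group mean and a score per library, which is RPKM rounded to whole numbers: all scores equalled the count over length and column total within 0.6%. The deposited log2 columns hold the authors' edgeR fold change and mean CPM, and the deposited p-value columns hold their test. The authors' mark equals a Benjamini-Hochberg value under 0.05 computed from their p-values, except for 1 bullfrog contig under it without the mark. In the zebrafish table the deposited fold change is vehicle over hormone, and its sign was turned. A nameless entry of the zebrafish table was left out, since it equals the sum of all others in all 6 libraries. All features had at least 1 CPM in at least 3 libraries, so a filter had been applied before deposit and filterByExpr removed none. All bullfrog lengths are multiples of 3, so they are coding lengths.

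The main test, fixed before the data were examined, was the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 with default settings, TMM scaling and Benjamini-Hochberg adjustment at 0.05, for hormone against vehicle and dorsal against ventral. The SE of a log2 fold change is its size over the square root of F. Levels are CPM with TMM factors, and scores and principal components use log2 CPM with a prior count of 2. Alternatives fixed beforehand were RLE scaling, DESeq2 1.42.0, no filter, the replicate number as a block, leaving out each library, a threshold of 0.01, a log2 fold change of at least 1 and, for lists, an estimated correlation and all records of a symbol. Alternatives added after seeing the data were the exact and likelihood ratio tests of edgeR, 2 other settings of its quasi-likelihood fit, limma 3.58.1 voom with and without quality weights, total count scaling, the authors' deposited calls, contigs summed by name stem, the inner retina score as a covariate in zebrafish, and the visual cycle list without cyp27c1.

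The 18 gene lists were fixed before the data were examined and were tested with camera at a preset correlation of 0.01 and with an estimated one, adjusted over the 18 lists. Where records share a symbol, the most abundant stood for the gene. The rule for named genes took cyp27c1, up to 8 genes on each side past the main test with a mean log2 CPM of at least 1 and groups that do not overlap, list members past it, and visual cycle, receptor and deiodinase genes whatever their p. Since the main test called 1 zebrafish record, the same rule was also applied, after the calls were seen, to genes past both DESeq2 and the authors' test. The 8 cone opsins were likewise named after their values were seen. The rule allows up to 2 abundant members of each list with no call. None were named on that ground, which was decided after values were seen. File symbols that are clone or locus names were replaced by the current symbol of the same accession in the RefSeq table of assembly GRCz12tu, which holds 12528 of the 18315 accessions; the file's symbol is given where each is introduced, except mipepb, which the file lists under a clone name.

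The fits were tested on simulated counts, drawn once per species, with 200 changed genes per species at 4 fold sizes, 50 each. For the 18315 zebrafish records the quasi-likelihood test recovered 6%, 68%, 90% and 100% of genes changed by a log2 of 1, 2, 3 and 5, with 11 unchanged genes among 143 calls. DESeq2 recovered 32%, 84%, 98% and 100%, with 46 unchanged among 203. The covariate fit recovered 4%, 70%, 88% and 100%, with 13 unchanged among 144. For the 25115 bullfrog contigs the quasi-likelihood test recovered 44%, 90%, 100% and 100%, with 9 unchanged among 176, and DESeq2 46%, 88%, 100% and 100%, with 16 among 183. In a simulation of 18 lists the moved list ranked 1, and none of the others passed. In all these simulations genes varied independently. The estimated correlation within the real lists ranged from 0.01 for the other cytochrome P450 genes to 0.7 for the melanin genes. The simulation therefore does not test false list calls in these data. Nor can the gene simulations give the recovered or unchanged shares among the real genes. The estimated biological coefficient of variation was 0.302 in zebrafish and 0.17 in bullfrog.

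The bullfrog contigs are not paired with gene names in the table, so the bullfrog cyp27c1, the bullfrog gene lists and the overlap of genes between species, which had been planned, were not computed. The reference tables used here cover zebrafish.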

Results

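RNA from the retinal pigment epithelium (RPE), the pigmented cell layer behind the photoreceptors that recycles vitamin A for vision, was sequenced in 2 animals that change their visual pigments. In zebrafish, 3 samples from fish given thyroid hormone for 3 weeks stood against 3 samples from fish given the vehicle. In the American bullfrog, 3 samples of dorsal RPE stood against 3 of ventral RPE, from the upper and lower part of the eye. Total counts per zebrafish library were 6647597, 12530697 and 11161495 with hormone and 11739178, 10668014 and 10582772 with vehicle, over 18315 transcript records. Bullfrog totals were 8589212, 10868432 and 9511205 in dorsal and 12000358, 11433616 and 9976021 in ventral libraries, over 25115 assembled contigs. The labels do not say that replicates came from separate animals, so p-values measure the spread between these samples, which may be technical. The series title names cyp27c1, a cytochrome P450 that makes vitamin A2 from vitamin A1, and the questions were which transcripts differed with hormone treatment in zebrafish and with position in the bullfrog eye.

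In zebrafish, cyp27c1 stood at 3261, 8943 and 6751 CPM (counts relative to the scaled library total) in the hormone libraries and at 183, 217 and 124 in the vehicle libraries. The group means were 6318 ± 2866 and 174.5 ± 47.3 CPM (SD, n = 3 each), a fitted difference of 36.2-fold (log2 fold change 5.18, SE 0.51). The lowest hormone library was 15-fold above the highest vehicle library. The quasi-likelihood test of edgeR, the main test, placed cyp27c1 outside the threshold of 0.05, at an adjusted p of 0.0571 over all records. Its unadjusted p in that test was 2.56e-05, and cyp27c1 had been set as a result of its own beforehand. Over the alternatives the adjusted p ranged from 6.79e-31, with DESeq2, to 0.46, without vehicle replicate 1, and it was 0.00895 without hormone replicate 1. An exact permutation test, two-sided, gave p = 0.1, the smallest that 3 against 3 libraries allow.

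**Figure D1:**
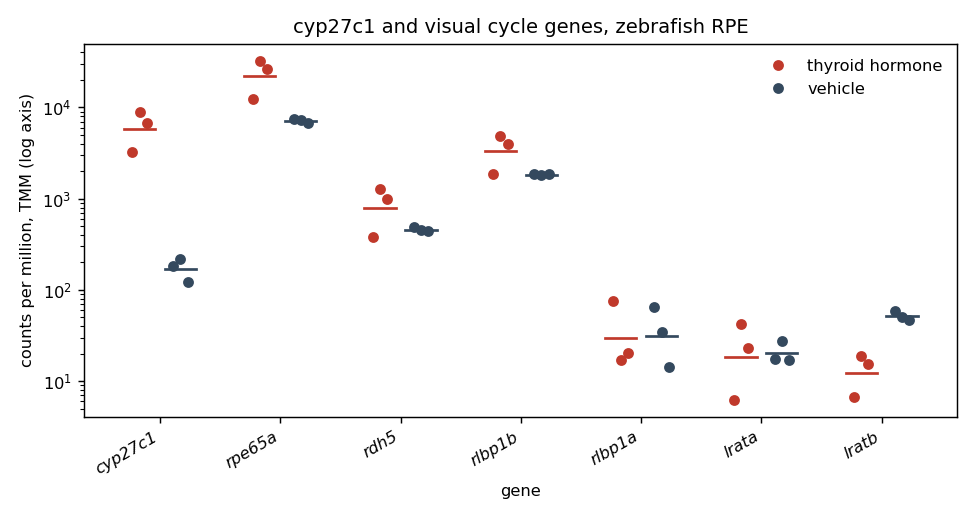
CPM on a log axis for cyp27c1 and 6 visual cycle genes in the zebrafish RPE, with 1 point per library and a line at the geometric mean of each group of 3. The hormone libraries of cyp27c1 lie between 3261 and 8943 and the vehicle libraries between 124 and 217.

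The quasi-likelihood test called 1 of the 18315 zebrafish records, dhrs12la (flj13639 in the file), named as a member of the short-chain dehydrogenase/reductase family. It rose from 0.72 ± 0.14 CPM with vehicle to 11.7 ± 0.19 with hormone (SD, n = 3 each), 16-fold, with an SE of 0.235 on the log2 scale and an edgeR adjusted p of 0.0175. In the vehicle libraries 3 counts equal 0.256 to 0.283 CPM, so the vehicle level rests on few reads. The hormone SD is smaller than 3 counts, which equal 0.239 to 0.451 CPM in the hormone libraries. The gene dhrs12la lost the call when any library other than hormone replicate 1 was left out, with adjusted p from 0.0956 to 0.297 and log2 fold changes from 3.834 to 4.096. The call was also lost with the replicate block (0.157, log2 fold change 4.004) and with limma voom (0.0566, log2 fold change 3.966). At an unadjusted p under 0.05 the same test had 1260 records. DESeq2 called 292 records, 166 higher and 126 lower with hormone, and the authors' deposited table marks 171, of which 150 were also called by DESeq2. In counts simulated at the spread of these libraries, 46 of 203 DESeq2 calls were of unchanged genes. The quasi-likelihood test had 11 of 143, and both shares were above 0.05 in this draw. The counts were drawn only once, so a share near 0.05 is uncertain. Simulated genes varied independently, while the first principal component of the real libraries held 50.3% of the variance and did not follow treatment. The simulation therefore cannot give the share of false calls among the 292 real DESeq2 calls. Without hormone replicate 1, the library with the lowest total, the quasi-likelihood test called 105 records, 79 higher and 26 lower; without any of the other 5 libraries it called 0, with 752 to 1180 records at an unadjusted p under 0.05.

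Genes past both DESeq2 and the authors' test, with all libraries of the groups apart, are given here as values, since none but dhrs12la passed the main test. Those with the smallest DESeq2 p above the vehicle level included gsdf (LOC100537308 in the file), a growth factor gene best known from gonads, at 934 ± 80.1 against 284 ± 11.9 CPM (SD, n = 3 each). The small GTPase gene rrad stood at 47.1 ± 10.2 against 12.9 ± 1.93 CPM, and impdh1b, for an enzyme of guanine nucleotide synthesis, at 69.5 ± 3.71 against 32.5 ± 2.78. The adenylate kinase gene ak4, the carboxypeptidase gene cpn1 and the nuclear receptor gene nr2f6b had log2 fold changes of 1.43, 1.34 and 1.39. On the lower side, htra1b, for a secreted serine protease, stood at 11.4 ± 3.64 CPM with hormone against 72.4 ± 21.1 with vehicle. The autophagy kinase gene ulk1a stood at 17.1 ± 2.94 against 53.8 ± 2.13 CPM, and wsb1, for a substrate receptor of an E3 ubiquitin ligase, at 32.7 ± 2.81 against 83.5 ± 6.51. The Kit ligand gene kitlga, the hypoxia-inducible factor gene hif1al, osgn1 (zgc:56005) and the mitochondrial peptidase gene mipepb had log2 fold changes of -1.22, -1.26, -1.66 and -1.63. The edgeR adjusted p of these 13 genes and of the rod gene pde6g ranged from 0.0571 to 0.396.

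The fixed list of 35 measured visual cycle and retinoid genes stood higher with hormone as a set (camera adjusted p = 2e-04; adjusted p = 0.68 with an estimated correlation), with 23 positive and 12 negative log2 fold changes. Other lists hold 5 of its members. None passed the edgeR test over all genes, with 3 past DESeq2, and 2 passed when adjusted over the list alone, cyp27c1 and lratb. Without cyp27c1 the other 34 genes had a camera adjusted p of 0.015, and 0.75 with an estimated correlation. The retinoid isomerase gene rpe65a, which makes 11-cis retinol, stood at 23630 ± 10170 against 7127 ± 403 CPM (SD, n = 3 each; log2 fold change 1.73, SE 0.46), with all hormone libraries above all vehicle libraries and an edgeR adjusted p of 0.426. The gene lratb, a paralog of the enzyme that esterifies retinol, stood at 13.6 ± 6.19 against 52.1 ± 6.66 CPM (log2 fold change -1.93, SE 0.36). For rlbp1b and rdh5, which carry and oxidise 11-cis retinol, log2 fold changes were 0.95 (SE 0.37) and 0.95 (SE 0.41), and for lrata and rlbp1a 0.20 and -0.002, the last being 0.009 with total count scaling. In hormone replicate 1, rdh5 stood at 384 CPM, below every vehicle library (437 to 485). There rlbp1b, at 1858 CPM, lay within the vehicle range (1804 to 1876). Of the named genes of this list, cyp27c1, rpe65a, rdh5, rlbp1b, lrata and lratb were lowest among the hormone libraries in replicate 1 and rlbp1a was highest there, the library with the highest inner retina score.

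Of 26 measured genes of thyroid hormone signalling, none passed over all genes in edgeR, 5 passed DESeq2 and 5 passed when adjusted over the list alone, all above the vehicle level, while 14 of the 26 log2 fold changes were positive and 12 negative (median 0.06; camera adjusted p = 0.03; adjusted p = 0.75 with an estimated correlation). The receptor gene thrab stood at 112 ± 7.44 against 58.6 ± 6.18 CPM (SD, n = 3 each), thraa at 181 ± 25.2 against 102 ± 13.8 and thrb at 273 ± 24.8 against 156 ± 19.4, with log2 fold changes of 0.93, 0.83 and 0.81. Besides these 3 receptors, dio3b and ncor1 passed over the list alone. The corepressor gene ncor1, named after its values were seen, stood at 1794 ± 55.2 against 1122 ± 50.8 CPM. The direct response gene klf9, also named after its values were seen, stood at 3.80 ± 1.22 against 6.98 ± 1.93 CPM, lower in every hormone library than in any vehicle library (log2 fold change -0.88, edgeR adjusted p = 0.651). The deiodinase gene dio3b (LOC798872 in the file), whose enzyme inactivates thyroid hormone, stood at 88.4 ± 14.9 against 27.5 ± 8.06 CPM (log2 fold change 1.69, SE 0.24). The activating deiodinase genes dio1 and dio2 had log2 fold changes of 0.09 (SE 0.43) and -0.99 (SE 0.47), the first being -0.02 with total count scaling. The list lost its call without hormone replicate 2 (camera adjusted p = 0.158) or 3 (0.0743) and without vehicle replicate 1 (0.155) or 2 (0.239), with all records of a symbol kept (0.0591) and with the inner retina score as a covariate (0.118). Of 23 other cytochrome P450 genes, 2 passed when adjusted over the list alone, cyp24a1 and cyp27a7. Of these cyp24a1, for the vitamin D 24-hydroxylase, stood at 350 ± 184 CPM with hormone against 24.5 ± 19.2 with vehicle (log2 fold change 3.84, SE 0.69, edgeR adjusted p = 0.228). Its log2 fold change ranged from 3.425 to 4.711 with 1 library left out. That list did not stand apart as a set (camera adjusted p = 0.51; 0.83 with an estimated correlation).

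Photoreceptor transcripts were abundant in these dissected RPE samples. The rod and cone lists had opposite signs, with mean log2 fold changes of -0.14 and 0.21. Of all libraries, hormone replicate 1 stood highest in both lists, at a mean log2 CPM of 9.68 for rods and 8.79 for cones. Hormone replicate 2 stood lowest in both, at 8.80 and 7.62, so the groups overlapped in each list. The 23 measured rod genes had 17 negative log2 fold changes (camera adjusted p = 0.0066; adjusted p = 0.83 with an estimated correlation), among them pde6g, for the inhibitory subunit of the rod phosphodiesterase, at 3942 ± 538 against 8189 ± 598 CPM (SD, n = 3 each). The rod list lost its call without hormone replicate 2 (camera adjusted p = 0.7) and without vehicle replicate 1 (0.0574) or 2 (0.0656). The 26 measured cone genes had 16 positive ones (camera adjusted p = 0.026; adjusted p = 0.89 with an estimated correlation), and 2 passed when adjusted over the list alone, opn1mw4 and thrb, which the thyroid list also holds. Without hormone replicate 1 the direction of the cone list turned (camera adjusted p = 0.824), and its call was lost without vehicle replicate 2 (0.0656) or 3 (0.427). Among the green cone opsins, opn1mw4 stood at 368 ± 86.8 against 84.6 ± 47.6 CPM and opn1mw3 at 716 ± 327 against 269 ± 65.9, while opn1mw1 stood at 24.0 ± 19.1 against 115 ± 100.2. The log2 fold changes were 2.12, 1.41 and -2.27, and that of opn1mw2 was -0.74. With 1 library left out, opn1mw4 ranged from 1.798 to 2.641 and opn1mw3 from 0.968 to 1.605. In the same fits opn1mw1 ranged from -3.067 to -1.27 and opn1mw2 from -1.649 to -0.306. Of the red cone opsins, opn1lw1 had a log2 fold change of 1.13 (SE 0.39) and opn1lw2 of 0.14 (SE 0.39); the ultraviolet and blue cone opsins opn1sw1 and opn1sw2 had -0.53 and -0.05. None of the 8 passed over all genes in edgeR, with 4 at an unadjusted p under 0.05 and 2, opn1mw4 and opn1mw3, past DESeq2. The opsin copies lie close in sequence, so reads may have been shared between them and their values are uncertain.

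**Figure D2:**
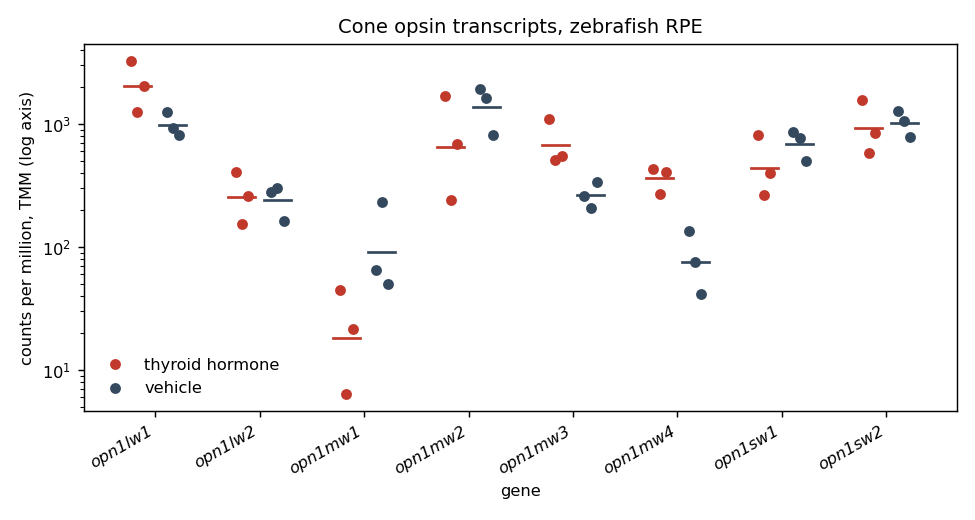
CPM on a log axis for 8 cone opsin transcripts in the zebrafish RPE, with 1 point per library and a line at the geometric mean of each group of 3. The hormone libraries of opn1mw4 lie above its vehicle libraries, and those of opn1mw1 below.

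Blood and immune genes stood lower with hormone as a set, with 19 of 23 log2 fold changes negative (camera adjusted p = 0.00011; adjusted p = 0.80 with an estimated correlation). The list mean was 3.55, 3.51 and 3.41 log2 CPM in the hormone libraries and 3.98, 3.44 and 4.49 in the vehicle libraries. Vehicle replicate 2 thus lay within the hormone range. The red cell anion exchanger gene slc4a1a stood at 6.16 ± 1.96 against 20.9 ± 10.7 CPM (SD, n = 3 each). The globin gene hbaa2 (si:ch211-5k11.6) stood at 3.35 ± 0.58 against 17.1 ± 12.5 CPM, with vehicle replicate 2, at 3.43, within the hormone range. The set no longer passed without vehicle replicate 3 (camera adjusted p = 0.105). Stress and immediate early genes had 22 of 30 log2 fold changes negative (camera adjusted p = 0.026; adjusted p = 0.83 with an estimated correlation), among them fosb, for an immediate early transcription factor, at 11.4 ± 3.60 against 55.4 ± 32.2 CPM. When adjusted over the list alone, 2 passed, fosb and socs3b (log2 fold change 1.03, named after its values were seen). The stress list lost its call without hormone replicate 1 (0.37) or 2 (0.158) and without vehicle replicate 2 (0.15) or 3 (0.359), and with the inner retina covariate (0.0777). The 14 dorsal eye genes had 11 positive ones (camera adjusted p = 0.042; adjusted p = 0.80 with an estimated correlation), and the call was lost without hormone replicate 1 (0.717) and without vehicle replicate 1 (0.0977) or 3 (0.174), and with the replicate block (0.0518). The 16 melanin genes, with 12 positive, did not pass (camera adjusted p = 0.082). Neither did the lists of RPE markers (0.92), inner retina neurons and Muller glia (0.55), choroid (0.2), sclera (0.73), iridophores and xanthophores (0.17), ventral eye (0.99), lipid synthesis (0.92), mitochondrial energy (0.27) and cell cycle (0.59), each value a camera adjusted p. Without hormone replicate 1 the melanin (1.5e-10), iridophore (0.00435) and inner retina (0.0137) lists passed. Without vehicle replicate 3 the cell cycle (0.0103), sclera (0.0279), choroid (0.0415), melanin (0.0415) and inner retina (0.0492) lists did, without hormone replicate 2 the choroid list (0.0176) and without hormone replicate 3 the mitochondrial list (0.0344). These calls used the preset correlation, and with all libraries the adjusted p of these 7 lists with an estimated correlation was 0.83 to 0.96. In the ventral eye list the mean log2 fold change was -0.07 and the median 0.13, with camera giving a lower direction. The inner retina score, the mean log2 CPM of that list, was 5.42, 4.31 and 4.58 in the hormone libraries and 5.20, 4.99 and 4.27 in the vehicle libraries.

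**Figure D3:**
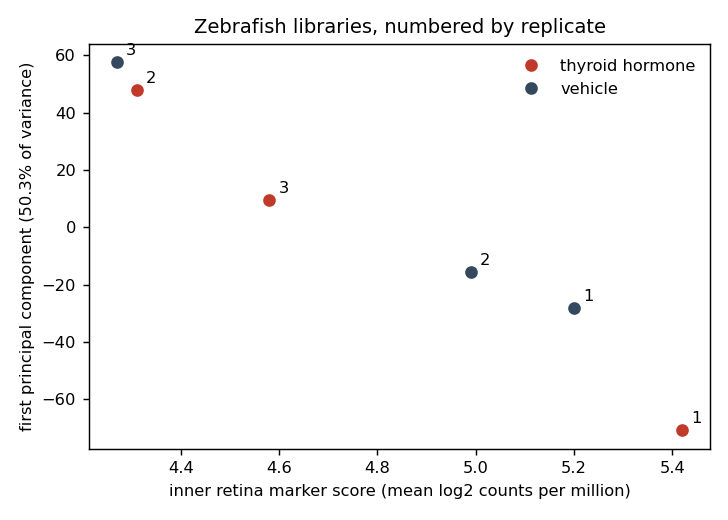
The first principal component of the zebrafish libraries, from log2 CPM, against the inner retina score in mean log2 CPM, with points numbered by replicate. Hormone replicate 1 has the highest score, 5.42, and the lowest component value, -70.9.

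In the bullfrog, 2801 of 25115 contigs differed between dorsal and ventral RPE at an adjusted p under 0.05 in the quasi-likelihood test of edgeR, 1448 higher in dorsal and 1353 higher in ventral. Among called contigs with larger differences more were higher in ventral: at a log2 fold change of at least 1 in size, 338 were higher in dorsal and 899 in ventral, at 2 or more 41 and 336, at 3 or more 17 and 57, and at 4 or more 9 and 12. Contigs carry no gene names in the deposited table, so no gene is named here and the bullfrog cyp27c1 was not analysed here. For the same reason markers of other eye tissues were not checked. Whether dorsal and ventral samples held different amounts of such tissue was not tested. The contig comp18080_c0_seq1|m.8975 was higher in dorsal, at 45.7 ± 1.65 against 7.70 ± 1.22 CPM, and comp45621_c0_seq1|m.26889 at 12.4 ± 1.14 against 0.50 ± 0.27 (SD, n = 3 each). Higher in ventral were comp24532_c0_seq1|m.17463, at 36.4 ± 4.76 against 1.28 ± 0.60 CPM in dorsal, and comp23010_c0_seq1|m.16163, at 51.8 ± 10.9 against 7.07 ± 0.46. These 4 contigs had the smallest p-values on each side, with adjusted p from 7.07e-05 to 0.000127. The most abundant contig among the 9 higher in dorsal at 4 or more, chosen after its values were seen and with a coding length of 1614 bases, stood at 2112, 2013 and 1654 CPM in dorsal and 72.1, 49.4 and 22.6 in ventral (log2 fold change 5.32, SE 0.38, adjusted p = 0.000206).

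**Figure D4:**
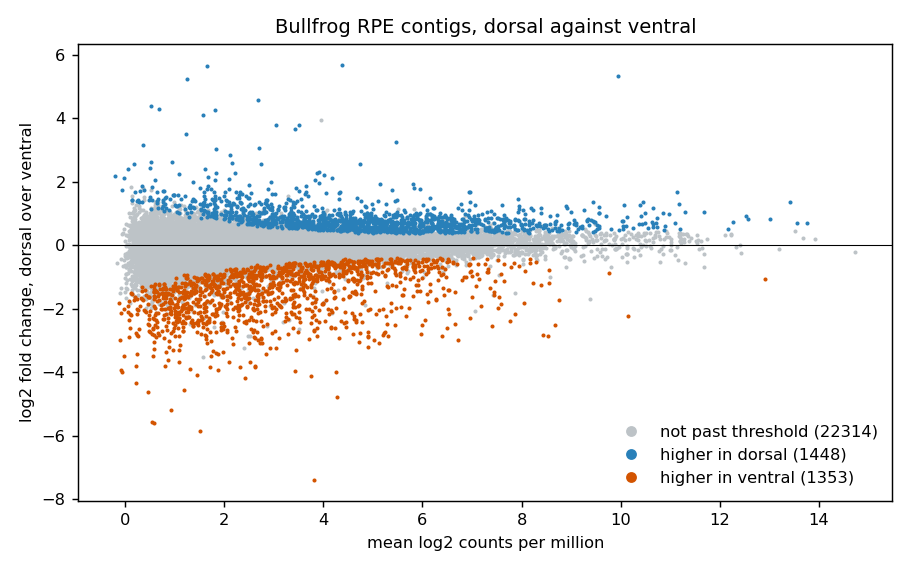
The log2 fold change, dorsal over ventral, of each bullfrog contig against its mean log2 CPM, with the 1448 contigs called higher in dorsal and the 1353 called higher in ventral in colour. Called contigs with a log2 fold change of 2 or more in size number 41 on the dorsal side and 336 on the ventral side.

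Groups did not overlap for 30.9% of bullfrog contigs, where chance gives 10%, and for 13.3% of zebrafish records. DESeq2 called 2520 bullfrog contigs, of which 2317 were among the 2801, and the authors' deposited table marks 3297, of which 2681 were. The split of directions depended on scaling: with total counts in place of TMM factors, 758 of 3214 called contigs were higher in dorsal and 2456 in ventral, and the median log2 fold change of all contigs moved from -0.01 to -0.18. With that scaling 34 contigs were higher in dorsal and 430 in ventral at a log2 fold change of 2 or more. Leaving out 1 library gave 991 calls without ventral replicate 2, 1133 without dorsal replicate 1, 1732 without ventral replicate 1 and 1863 without dorsal replicate 3.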

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

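The exact, likelihood ratio, voom, quality weight, total count, covariate, legacy-off, robust and deposited-call settings, contigs summed by name stem and the visual cycle list without cyp27c1 were chosen after seeing the data. The zebrafish count of 1 became 292 with DESeq2, 210 with the exact test (199 with dispersion estimated without the design), 217 with the likelihood ratio test, 501 with quality weights, 435 with the covariate, 8 with total counts and 171 in the authors' deposited table. It became 0 with voom, with 1226 records at an unadjusted p under 0.05, and 0 at a threshold of 0.01. It was 1 with RLE scaling, no filter, robust fitting, legacy off and the fold threshold; the filter removed no record, so that setting tests nothing. Leaving out 1 library gave 0 to 105. Of the 40 named zebrafish genes, 1 passed the main test, 27 passed DESeq2 and 24 the covariate fit. Many of the 40 were named for passing DESeq2 and the authors' test. The DESeq2 count largely follows from that choice, and the covariate count is not independent of it.

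The cyp27c1 log2 fold change ranged from 4.85 to 5.49 with 1 library left out, with adjusted p from 0.00895 to 0.46. It passed at 5.18 with DESeq2 and the exact and likelihood ratio tests, 5.18 in the authors' deposited table, 5.14 with quality weights, 5.08 with total counts and 5.04 with the covariate, with adjusted p from 6.79e-31 to 0.043, and stayed outside with RLE scaling (0.0619), robust fitting (0.0713), legacy off (0.0662), the block and voom (0.0566). The cause was not tested.

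The bullfrog count of 2801 ranged from 991 to 2765 with 1 library left out, and became 825 at a threshold of 0.01 and 1237 with a log2 fold change of at least 1. Of the 7 lists past camera in zebrafish, 0 passed with an estimated correlation and 3 at 0.01, 3 to 8 with 1 library left out, and 6 with all records of a symbol, where the thyroid hormone list lost its call (0.0591). The covariate left 5 past camera: the thyroid hormone list lost its call (0.118) with a mean log2 fold change of 0.072 against 0.098 without it, and the stress list (0.0777) with -0.334 against -0.318. The fold threshold has no meaning for lists and was not run there. Results planned on bullfrog gene names, including the genes called in both species, were not run.

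The replicate numbers did not clearly pair the samples. Deviations of same-numbered libraries correlated at 0.46, -0.39 and 0.10 in zebrafish and at -0.05, 0.31 and 0.22 in bullfrog. Not every sample correlated best with its own number. Bullfrog dorsal replicates 2 and 3 and zebrafish hormone replicates 1 and 3 did, so a pairing stays possible in both species. With the replicate block, 0 zebrafish records (1231 at an unadjusted p under 0.05) and 3634 bullfrog contigs were called, 6 lists passed (the dorsal eye list lost its call, 0.0518), and cyp27c1 had a log2 fold change of 5.10 with an adjusted p of 0.205, and dhrs12la lost its call (0.157) at a log2 fold change of 4.004.

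For the genes and lists here the direction turned in at least 1 setting; for lists this is camera's direction, and the mean printed beside it can keep its sign. With the block, dio1 had -0.07, lrata -0.079 and the ventral eye list a mean of 0.003. With voom dio1 had -0.10 and lrata -0.056, with quality weights opn1lw2 had -0.15, and with total counts dio1 had -0.017 and rlbp1a 0.009. With the covariate dio1 had -0.12, lrata -0.16, rlbp1a 0.005 and the ventral eye list -0.008; with all records of a symbol that list had -0.057. With DESeq2 rlbp1a had 0.006 and the RPE marker list -0.055; rlbp1a had 0.007 with the exact and likelihood ratio tests and 0.01 in the authors' deposited table. With 1 library left out, dio1 ranged from -0.146 to 0.472, lrata from -0.484 to 0.647, opn1lw2 from -0.269 to 0.417, opn1sw2 from -0.53 to 0.219 and rlbp1a from -1.007 to 0.641. List means ranged from -0.139 to 0.089 for RPE markers, -0.084 to 0.601 for cell cycle, -0.068 to 0.122 for lipid synthesis, -0.141 to 0.432 for cones (past camera with all libraries), -0.473 to 0.182 for inner retina, -0.206 to -0.006 for mitochondrial energy, -0.005 to 0.572 for sclera and -0.242 to 0.229 for ventral eye; the cause was not tested. The means of the rod list (-0.442 to 0.027) and the choroid list (-0.01 to 0.562) crossed 0 while the direction in camera stayed.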

Other observations

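The genes and tests of this part were chosen after the results were seen, except the thinning test and the counts over other splits, and the limit of 2 cone opsins was set with their number known. Among the 5 measured cyp27a genes, relatives of cyp27c1, 4 stood lower in every hormone library than in any vehicle library, while none passed the main test and 1, cyp27a7, passed DESeq2. It stood at 15.7 ± 0.74 against 25.3 ± 0.91 CPM, and cyp27a5 at 5.96 ± 1.95 against 11.1 ± 1.28 (SD, n = 3 each); reads shared between these copies would make their values uncertain. Of 30 measured clock genes, 2 passed DESeq2 and none the main test: rorcb at 76.7 ± 10.1 against 152.5 ± 17.8 CPM and nfil3 at 7.57 ± 1.19 against 15.0 ± 1.54.

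The first principal component of the zebrafish libraries held 50.3% of the variance and did not follow treatment: its values were -70.9, 47.7 and 9.4 with hormone and -28.2, -15.6 and 57.5 with vehicle, while the second (20.7%) parted the groups, at -21.4, -29.5 and -33.5 against 29.3, 29.3 and 25.8. Different amounts of neural retina carried over with the RPE are a candidate explanation: the inner retina score correlated with the component computed without the 3 retina lists (Pearson r = -0.983, exact permutation p = 0.00139; Spearman rho = -1, p = 0.00278; both 0.00278 after Benjamini-Hochberg adjustment over the 2; r = -0.977 without the 2 samples farthest from the median score). Of the list's 26 measured genes, 1 is in another list, trpm1b (zgc:162329 in the file), the most abundant at 1077 ± 450.7 against 1405 ± 255.5 CPM, followed by glula at 742 ± 79.8 against 652.5 ± 58.2. Only the listed genes were left out of the component, so retina genes outside the lists could remain in it. The score was also chosen after the component was seen. The p-values therefore do not measure support for carry-over. Depth was argued against, since thinning all libraries to the lowest total left 0.974 of the component's range. No biological explanation of the component was tested.

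The higher cyp27c1 in hormone libraries was set against a larger share of pigment epithelium. The other 73 genes of the visual cycle, melanin and RPE lists had a median log2 fold change of 0.2 (SD 0.71). These lists also hold genes of other cells, such as trpm1b of the inner retina list, so the median does not measure that share. The highest of the 73 was 1.73, for rpe65a, against 5.18 for cyp27c1, which argues against that share as the only cause. A smaller difference in the share stays open. Hormone treatment, the difference the design names, stays as a hypothesis. The main test left cyp27c1 outside its threshold when adjusted over all records, at an unadjusted p of 2.56e-05.

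The cone opsins were set against different amounts of neural retina carried over, with the inner retina score as a covariate. The score did not part the groups, and its genes had a mean log2 fold change of -0.01. The covariate could thus narrow the spread but hardly move the fold changes, so the fit cannot decide on carry-over. Of all 8, 2 passed the threshold in that fit. For opn1mw4 the log2 fold change was 2.28 (SE 0.27, adjusted p = 0.0114), against 2.12 (SE 0.44, 0.284) without the covariate. For opn1lw1 it was 1.09 (SE 0.20, adjusted p = 0.0397), against 1.13 (SE 0.385, 0.612) without. The other 6 had adjusted p from 0.0754 to 0.811 in that fit, among them opn1mw1 at -2.39 (SE 0.56, 0.0782) and opn1mw2 at -0.93 (SE 0.27, 0.145). The log2 ratio of opn1mw3 and opn1mw4 to opn1mw1 and opn1mw2 was 2.16 ± 0.96 with hormone and -1.32 ± 0.83 with vehicle (SD, n = 3 each), and that of opn1lw1 to opn1lw2 was 3 ± 0.02 and 2.03 ± 0.36, but these ratios were picked because their genes moved apart. Reads shared between the copies, the part of the retina carried over and a hormone effect stay open.

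The 6 libraries of a species make 10 splits into 3 and 3, too few for a share under 0.05. The counts of splits given here include the real one. In zebrafish, 2 splits gave at least as many calls as the real one in the main test (real 1, highest other 1153). The count was also 2 in DESeq2 (real 292, highest other 2600). The split with most calls set hormone replicate 1 and vehicle replicates 1 and 2 against the rest, which points to a structure of the samples along the first principal component. With the inner retina score as a covariate, the only split with as many calls was the real one (real 435, highest other 1). Of the 435, 234 were also called by DESeq2. That covariate was chosen after the component was seen. In bullfrog, too, the only split with as many calls was the real one (real 2801, highest other 0).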
